A study of Mus musculus with 12 samples.

How the data were processed

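Total RNA from renal cortex of ICGN and ICR mice at 4 and 8 weeks was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols, with 3 arrays in each of the 4 groups of strain and age. Cortex was cut from slices kept in RNAlater and RNA was isolated on RNeasy columns, per the labels' protocols. The values are the authors' deposited signal intensity per probe set on a linear scale, computed with MAS5 per the submitters' processing notes (version not given in the sources used here). In the deposited table the mean signal after trimming 2% at each end was 100.0 in every 4-week array and 500.0 in every 8-week array, so the arrays of each age had been scaled to a target of their own. Deposited levels of the 2 ages are therefore not on one scale. The table held 45101 probe sets, 64 of them controls. The array annotation given here named 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Gene IDs of 34754 of the named probe sets matched the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols, and 204 kept the annotation's symbol. Genes without a named probe set, several known kidney genes among them, were not analysed here. No coordinates are given, since the build of the annotation is not given in the sources used here.

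The following was computed from those signals with R 4.3.3 and limma 3.58.1. Each array was scaled to the common median of 40.4 because deposited array medians differed by over 0.5 on the log2 scale. Values were taken as log2(signal + 9), the offset being the 25th percentile of the table, so fold changes are on that scale and understate the change of dim genes. A probe set was tested if it lay above its own array median in at least 3 of 12 arrays, which left 24827 probe sets, 21839 with 1 symbol. Control probe sets and those with no or several symbols were left out of the gene counts. The probe set with the highest mean stood for a gene, those with the suffix _x_at coming last, and 12386 genes were tested. Probe sets of one gene were called in both directions for 5 genes in the strain comparison at 4 weeks and 34 at 8 weeks, and for 135 and 72 in the age comparisons of ICR and ICGN.

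One linear model with 4 group means was fitted to all 12 arrays (8 residual degrees of freedom), and limma's moderated test with a mean-variance trend gave 6 contrasts: the strain difference at 4 weeks, at 8 weeks and averaged over the ages, the interaction, and the age change in each strain. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p of 0.05 or less. Fold changes are printed after subtraction of the median fold change of the contrast, while the test is on the value before that subtraction. The verbs rose and fell are kept for called genes. In a strain comparison they mean higher or lower in ICGN than in ICR at that age, not a change over time. Of 32 gene lists, all but neutrophil, which had fewer than 2 tested genes, were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry: tensin family, podocyte, glomerular basement membrane, endothelial, mesangial and smooth muscle, fibrosis and matrix, tubular injury, proximal tubule, fatty acid oxidation, oxidative phosphorylation, loop, distal and collecting duct, macrophage and dendritic cell, lymphocyte and plasma cell, neutrophil, chemokine and cytokine, antigen presentation, interferon response, complement, cell cycle, cholesterol synthesis, oxidative stress, unfolded protein response, renin-angiotensin and erythropoietin, hypoxia response, immediate early, male-biased, female-biased, sex chromosome, adipocyte, adrenal, blood and erythroid, and inner medulla genes. Of 711 entries 643 were named by the annotation. Where the camera result at the preset correlation was lost with an estimated one, that p is printed. Other splits of the same arrays passed nearly as many lists or more at the preset correlation, so the counts of called genes and the estimated correlation carry the statements on lists. A count for a list has to be read beside the calls over all 12386 genes. In the strain comparisons these were 198 higher and 171 lower at 4 weeks, and 1054 higher and 3226 lower at 8 weeks.

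The scaling rule, the filter, the lists, the alternatives and the rule for the genes named were set before the data were examined. That rule took Tns2 and its family, the 10 highest and 10 lowest called genes of each strain comparison whose 3 arrays a group do not overlap, up to 4 called members of each list (3 in the age comparisons), the 5 highest and lowest of the interaction, the 8 highest and lowest of each age comparison, and the 10 highest and lowest of the mean among genes called at both ages. A part of those it names is printed. Alternative settings were no offset or 4 times the offset, quantile normalization, centring on the median of the tested genes, no filter or a filter at the 75th percentile, every probe set on its own, the mean of a gene's probe sets, no variance trend, a fit to the compared groups alone, replicate number as a block, each array left out in turn, and an added limit of a log2 fold change of 1. The authors' scaling with both ages brought to one target was added after seeing the data. The fit was tested on simulated data (1 simulated set, whose values vary with the random draw) for the 8-week strain comparison over 12386 genes, 200 of them changed. It recovered 34.2% of genes changed 1.5-fold, 89.1% of those changed 2-fold and 59 of 60 changed 4-fold, with 12 of 154 calls on unchanged genes (7.79%). The simulated noise was independent between genes and held no scaling error between arrays. Far fewer genes were changed than the 4280 called in the real comparison, so these rates need not hold there. Both of 2 simulated list shifts were recovered by camera with noise that was independent between genes. Bootstrap intervals used 10000 draws of genes, with the arrays held fixed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.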

Results

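Transcript levels were measured in the renal cortex of ICGN mice, a strain derived from ICR stock that develops a hereditary nephrotic syndrome and carries a mutation of Tns2, and of ICR mice, the normal strain. Cortex was taken at 4 and at 8 weeks of age, with 3 Affymetrix Mouse Genome 430 2.0 arrays per strain and age and 12 arrays in all. The labels number the replicates without saying how many mice each holds, so the p-values measure the spread between these samples. Their number, 3 a group, limits the precision of every value. Array medians as deposited lay between 17.4 and 19.0 at 4 weeks and between 75.3 and 108 at 8 weeks, and all arrays were brought to a common median. Log2 values of arrays from one group correlated with r between 0.977 and 0.988 across genes. The first principal component held 35.2% of the variance and the next 27.4%. The 4 groups lay apart on the pair. All 12 arrays gave signal for the Y-linked genes Eif2s3y, Uty and Kdm5d, while no Xist probe set exceeded 70.3. Log2 fold changes are given relative to the median tested gene of the comparison, with the standard error of the fit, and signals as mean ± SD (n = 3).

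The strain comparison at 4 weeks asks how the ICGN cortex differed from the normal one at the younger age. Tns2, whose product is an adaptor protein of podocytes and other cells, was lower in ICGN, with a signal of 78.2 ± 15.9 against 332 ± 12.96 in ICR (log2 fold change -1.96 ± 0.22, limma adjusted p = 2.0e-04). Its relatives Tns1 (0.02) and Tns3 (-0.30) did not pass the test, so 1 of 3 tensin genes was called (camera adjusted p = 0.00806, and adjusted p = 0.0709 with an estimated correlation). The transcript of kidney injury molecule 1, Havcr1, rose most, from 59.5 ± 8.51 in ICR to 894 ± 354 in ICGN, or 12.8-fold on the log scale used. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, was 10.1-fold higher, Chil4 8.86-fold, Igfbp1 5.63-fold, the chemokine Ccl5 5.63-fold and Cyp24a1, the enzyme that inactivates vitamin D, 5.56-fold.

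Of 27 tubular injury genes tested, 11 rose and 0 fell (15 adjusted over the list alone; camera adjusted p = 2.7e-17, and adjusted p = 0.0704 with an estimated correlation). Beside Havcr1 and Hmox1 they included Lcn2 (1.86 ± 0.34) and Ccl2 (1.85 ± 0.34). Among 26 macrophage and dendritic cell genes 12 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 8.7e-19, and adjusted p = 0.0704 with an estimated correlation), with Mpeg1 at 1.46 ± 0.20, Ms4a7 at 1.32 ± 0.20 and the complement component C1qa at 1.26 ± 0.19. Chemokine and cytokine genes rose in 6 of 26 cases (13 adjusted over the list alone; camera adjusted p = 4.7e-11, and adjusted p = 0.0704 with an estimated correlation), among them Cxcl10 (1.56 ± 0.29) and Il1b (0.90 ± 0.21). Antigen presentation genes rose in 6 of 16 cases (11 adjusted over the list alone; camera adjusted p = 1.5e-14, and adjusted p = 0.0709 with an estimated correlation). Cd74, the invariant chain of class II molecules, stood at 1.57 ± 0.24 and H2-Eb1 at 1.72 ± 0.28. H2-D1 was called higher (1.56), as were 4 of its 7 probe sets in all, while 2 were called lower. Of 21 interferon response genes 3 rose, Iigp1 (1.41), Gbp2 (0.90) and Irf1 (0.57), with 3 adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.688 with an estimated correlation).

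The largest falls at 4 weeks were in C1s1, a serine protease of the complement system (17.4-fold lower), and Dnajc18, a co-chaperone (11.8-fold lower). Cd99 was 5.91-fold lower, Snap91 4.70-fold, the proton pump subunit gene Atp12a 4.01-fold, Ptpn22 4.00-fold and the proapoptotic gene Bik 3.59-fold. The calcium-binding parvalbumin gene Pvalb fell 3.88-fold and the thiazide-sensitive cotransporter gene Slc12a3 2.14-fold, while Calb1, which like these is expressed in the distal convoluted tubule, did not pass (-0.24). Of 27 genes of the loop of Henle, distal tubule and collecting duct 1 rose and 2 fell (camera adjusted p = 0.811). Of 45 proximal tubule genes 2 rose, Cyp24a1 and Slc26a1 (0.93), and 0 fell (camera adjusted p = 0.106). Of 20 podocyte genes 1 rose, Sema3g (1.03 ± 0.18), and 0 fell (camera adjusted p = 0.00343, and adjusted p = 0.459 with an estimated correlation). Of 39 fibrosis and matrix genes Tgfbi (0.67), Vim (0.63) and Col18a1 (0.49) rose, and Col3a1 (-0.50) was called lower, a call lost under quantile normalization and the authors' scaling (camera adjusted p = 0.892). At this age 2 of 12 complement genes fell, with a median of 0.10, a mean of -0.14 and a test pointing up (camera adjusted p = 0.892), and 1 of 6 female-biased genes fell (camera adjusted p = 0.00115, and adjusted p = 0.0704 with an estimated correlation). No member of the basement membrane, endothelial, mesangial and smooth muscle, oxidative phosphorylation, fatty acid oxidation or cholesterol synthesis lists passed the test at 4 weeks. As a list, oxidative phosphorylation was lower (camera adjusted p = 0.036, and adjusted p = 0.84 with an estimated correlation), but its direction turned under quantile normalization (adjusted p = 0.667). Of 9 lymphocyte and plasma cell genes 2 rose, Blnk (0.71) and Ptprc (0.70; camera adjusted p = 0.0027, and adjusted p = 0.0709 with an estimated correlation). Of 16 immediate early genes, a list set as a check on handling of the tissue, 2 rose, Egr1 (1.16) and Myc (1.00; camera adjusted p = 0.0116, and adjusted p = 0.642 with an estimated correlation). None of 9 adipocyte genes was called, with a list median of -0.74 (camera adjusted p = 0.0109, and adjusted p = 0.438 with an estimated correlation), and Alas2 fell (-0.96) among 6 blood and erythroid genes (camera adjusted p = 0.0471, and adjusted p = 0.589 with an estimated correlation). Of 36 cell cycle genes Rrm2 fell (-0.85), and 35 did not pass (camera adjusted p = 0.00102, and adjusted p = 0.642 with an estimated correlation).

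For Chil4, Ccl5, Lcn2, Ccl2, Ms4a7, Il1b, C1s1, Dnajc18, Atp12a and Bik all 3 arrays of at least 1 group lay at or below their array median, so the size of these changes depends on the offset. In total 198 of 12386 genes were higher and 171 lower in ICGN at 4 weeks (limma, adjusted p of 0.05 or less), 83 and 60 of them by at least a log2 fold change of 1. Centring on the median of the tested genes gave 255 higher and 259 lower, quantile normalization 339 and 221, and the authors' scaling 338 and 205. The groups did not overlap for 22.8% of genes, against 10% by chance. The count fell to 167 without ICGN replicate 2, to 191 without ICGN replicate 1 and to 234 without ICR replicate 2. Without ICGN replicate 3, 129 were higher and 144 lower, and without ICR replicate 3, 143 and 105. No list passed its test with an estimated correlation, while at the preset one another split of the 6 arrays passed 12 lists against 14 for the strains. The 18S ribosomal RNA control read 626 ± 40.8 in ICGN and 893 ± 44.7 in ICR (exact permutation test, two-sided p = 0.1).

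**Figure D1:**
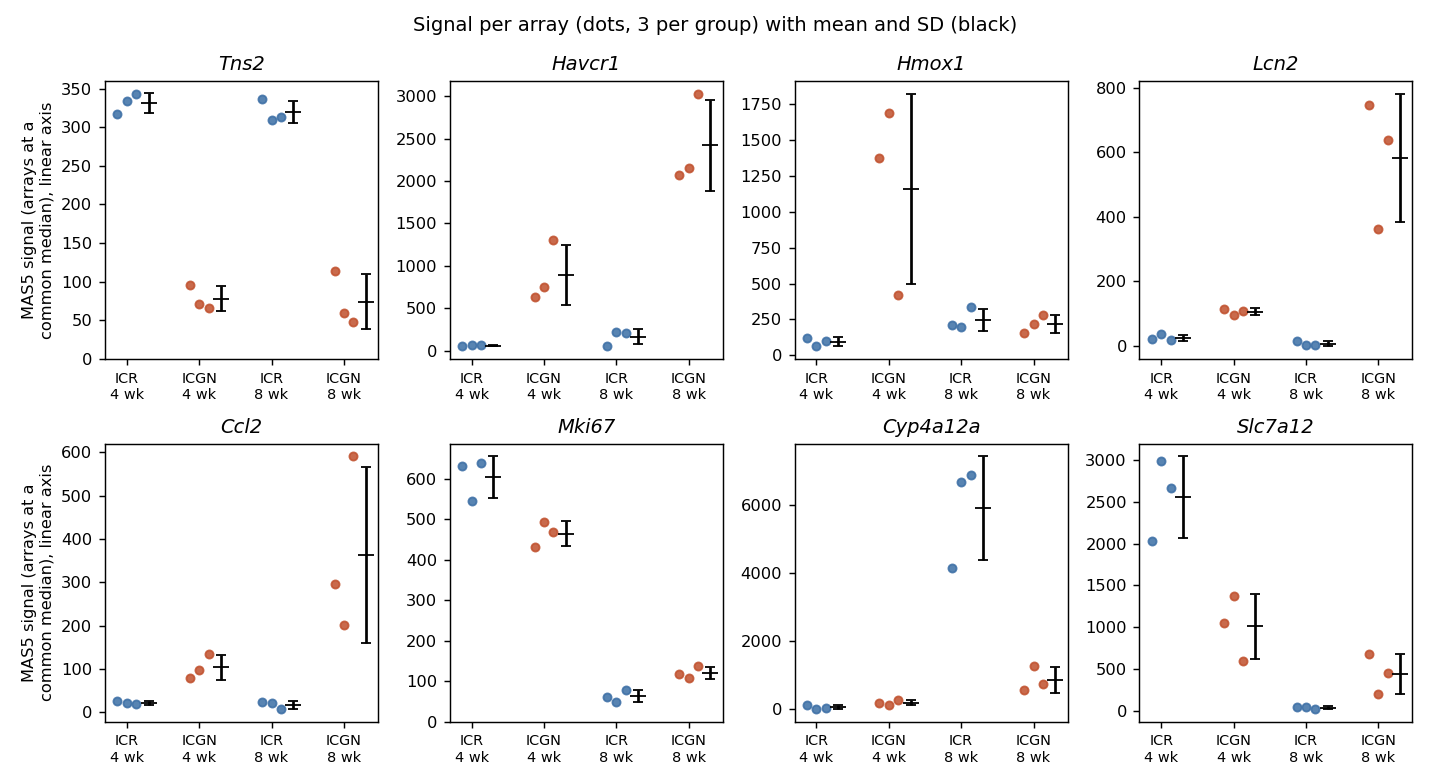
MAS5 signal on a linear axis, with all arrays at a common median, for 8 genes in the 4 groups; dots are the 3 arrays of a group, and the black bar is the mean with its SD. Tns2 lies lower in the ICGN arrays at both ages, Havcr1 higher at both ages and Hmox1 higher at 4 weeks, while Cyp4a12a lies lower in ICGN at 8 weeks, and Slc7a12 lies lower in ICGN at 4 weeks and higher at 8 weeks.

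At 8 weeks the same question was asked of older mice. Tns2 was again lower in ICGN (74.2 ± 35.2 against 319.9 ± 14.6; log2 fold change -1.88 ± 0.22, adjusted p = 1.2e-05). Lcn2, which encodes the injury marker lipocalin 2, stood at 583 ± 199 in ICGN and 5.71 ± 8.20 in ICR (adjusted p = 1.6e-07). Havcr1 was 18.2-fold higher, the monocyte chemoattractant gene Ccl2 14.8-fold, the adhesion molecule gene Vcam1 12.6-fold, the ubiquitin-like gene Ubd 23.3-fold, Gdpd3 26.2-fold and the diamine oxidase gene Aoc1 16.3-fold. The class II genes H2-Ea and H2-DMb2 were 70.1-fold and 10.5-fold higher, and 2 of the 3 ICR arrays held H2-Ea at or below their array median.

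Tubular injury genes rose in 22 of 27 cases and fell in 0 (24 adjusted over the list alone; camera adjusted p = 5.4e-25, and adjusted p = 0.048 with an estimated correlation). Macrophage and dendritic cell genes rose in 23 of 26 and fell in 0 (24 adjusted over the list alone; camera adjusted p = 3.7e-25, and adjusted p = 0.048 with an estimated correlation), with Ctss at 2.35 ± 0.18, Mpeg1 at 2.28 ± 0.20, Ms4a7 at 2.23 ± 0.20 and C1qc at 2.19 ± 0.20. Chemokine and cytokine genes rose in 18 of 26 and fell in 2 (18 adjusted over the list alone; camera adjusted p = 8.1e-13, and adjusted p = 0.048 with an estimated correlation), including Cxcl2 (2.83 ± 0.33) and Cxcl10 (2.42 ± 0.29). Fibrosis and matrix genes rose in 27 of 39 and fell in 1 (30 adjusted over the list alone; camera adjusted p = 3.8e-20, and adjusted p = 0.048 with an estimated correlation). The metalloproteinase inhibitor gene Timp1 was at 2.28 ± 0.32, and the collagen genes Col12a1 and Col8a1 were at 1.75 ± 0.18 and 1.74 ± 0.22. Antigen presentation genes rose in 14 of 16 (14 adjusted over the list alone; camera adjusted p = 6.2e-13, and adjusted p = 0.133 with an estimated correlation), with Cd74 at 2.23 and H2-Ab1 at 1.64. Interferon response genes rose in 16 of 21 (16 adjusted over the list alone; camera adjusted p = 2.8e-12, and adjusted p = 0.17 with an estimated correlation), among them Gbp2 (1.62), Irf7 (1.53) and Oasl2 (1.43). Of 12 complement genes 4 rose, including Cfi (1.78) and Serping1 (1.15), and C1s1 fell (-3.92; camera adjusted p = 0.0871). Immediate early genes rose in 9 of 16 and fell in 1 (9 adjusted over the list alone; camera adjusted p = 5.2e-07, and adjusted p = 0.17 with an estimated correlation), with Fos at 3.27 ± 0.33 and Egr1 at 2.56 ± 0.24. That list was set as a check on handling of the tissue, which cannot be told apart from a strain difference here. Cell cycle genes rose in 9 of 36 (7 adjusted over the list alone; camera adjusted p = 4.0e-09, and adjusted p = 0.219 with an estimated correlation), and in 21 when arrays were centred on the median of the tested genes, with Bub1 at 1.09 and Mki67 at 1.04.

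At 8 weeks, of 45 proximal tubule genes 29 fell (31 adjusted over the list alone; camera adjusted p = 8.4e-05, and adjusted p = 0.478 with an estimated correlation), among them Acsm3 (-1.79 ± 0.38), Acsm1 (-1.04 ± 0.16) and the organic anion transporter gene Slc22a6 (-0.95 ± 0.16), while Cyp27b1, which encodes the enzyme that activates vitamin D, rose 6.53-fold. Oxidative phosphorylation genes fell in 30 of 34 (31 adjusted over the list alone; camera adjusted p = 8.9e-07, and adjusted p = 0.478 with an estimated correlation), by a median log2 fold change of -0.28, with Ndufs1 at -0.50 and Sdhb at -0.42. Of 27 loop, distal and collecting duct genes 1 rose and 10 fell (camera adjusted p = 0.353), including Pvalb (-2.75 ± 0.18), Egf (-1.39 ± 0.19) and Slc12a3 (-1.01 ± 0.18). With arrays centred on the median of the tested genes 4 of them rose and 7 fell. Cholesterol synthesis genes fell in 9 of 19 and rose in 1 (9 adjusted over the list alone; camera adjusted p = 0.0174, and adjusted p = 0.444 with an estimated correlation), with Idi1 at -1.76 and Cyp51 at -1.43. Fatty acid oxidation genes went both ways, with 3 higher, including Cyp4a14 (11.2-fold) and Acot1 (2.77-fold), and 13 lower of 31 (median -0.12 and mean 0.06, the test pointing down; camera adjusted p = 0.353). Endothelial genes fell in 11 of 15 (13 adjusted over the list alone; camera adjusted p = 2.5e-04, and adjusted p = 0.197 with an estimated correlation), with the VEGF receptor genes Kdr at -0.95 ± 0.11 and Flt1 at -0.70 ± 0.11. Of 20 podocyte genes 4 rose, including Nes (1.15) and Cdkn1c (1.00), and 1 was called lower (camera adjusted p = 0.013, and adjusted p = 0.412 with an estimated correlation). Among 16 basement membrane genes 5 rose, including Agrn (1.01) and Col4a1 (0.69), and 2 fell, including Col4a3 (-0.67) (camera adjusted p = 0.0943). Mesangial, pericyte and smooth muscle genes rose in 4 of 14, including Tagln (1.05) and Pdgfrb (0.76), and fell in 1 (camera adjusted p = 9.5e-04, and adjusted p = 0.219 with an estimated correlation).

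Genes known to be expressed at a higher level in male kidneys fell in 13 of 14 cases at 8 weeks (13 adjusted over the list alone; camera adjusted p = 8.4e-05, and adjusted p = 0.378 with an estimated correlation). Cyp4a12a stood at 864 ± 375 in ICGN and 5912 ± 1532 in ICR, and the transporter gene Slco1a1 at 1318 ± 681 and 7016 ± 720.4. Of 6 female-biased genes Cyp4a14 (3.48) and Slc7a12 (3.31) rose and Slc22a7 (-3.27) and Rnf24 (-1.79) fell (median -0.01 and mean 0.28, the test pointing up; camera adjusted p = 0.529). Among the largest falls otherwise were those of C1s1 (15.1-fold), Apobec2 (12.5-fold), Rbm45 (7.71-fold), Tc2n (7.48-fold), Bik (7.25-fold), Aspdh (7.17-fold) and the carnosinase gene Cndp1 (5.60-fold). The angiotensin-converting enzyme gene Ace fell (-0.93) and Agt rose (0.67) among 5 genes of the renin-angiotensin list (camera adjusted p = 0.689). In the oxidative stress list the NADPH oxidase genes Cybb (1.65), Ncf4 (1.01) and Ncf1 (0.96) rose and 11 of 25 fell (median -0.16 and mean 0.01, the test pointing down; camera adjusted p = 0.509). Of 18 hypoxia response genes 9 fell, Vegfa (-0.58) among them, and Egln3 rose (0.90; camera adjusted p = 0.0945). In the unfolded protein response list 2 genes rose, Atf3 (2.18) and Asns (1.00), and 7 of 23 fell (median -0.06 and mean 0.06, the test pointing down; camera adjusted p = 0.529).

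Lists of other cells and tissues were read beside these groups. Of 9 lymphocyte genes 3 rose, including Ptprc (1.52) and Thy1 (1.00), and the plasma cell genes Jchain (-2.23) and Mzb1 (-0.80) fell (median 0.07 and mean -0.03, the test pointing up; camera adjusted p = 0.236). The adipocyte list, 9 genes of which Lpl and Pck1 are also expressed in kidney, had a median of -1.44 and 4 calls (camera adjusted p = 0.0265, and adjusted p = 0.378 with an estimated correlation), with Lpl at -1.45 and Retn at -0.84. The Pck1 call was lost under all 3 other scalings. Blood and erythroid genes fell in 3 of 6, Alas2 most (-1.10; camera adjusted p = 0.511). The inner medulla list held 1 call, Mal (0.65), of 9 (camera adjusted p = 0.182), the adrenal list 1 of 3, Dbh (-0.90; camera adjusted p = 0.689), and the sex chromosome list 0 of 4 (camera adjusted p = 0.34). The Dbh call was lost under the authors' scaling. Fewer than 2 genes of the neutrophil list were tested, so the list has no value. The signal ratio of the 3' to the 5' Actb control probe sets was 1.61 ± 0.0376 in ICGN and 1.94 ± 0.210 in ICR at 8 weeks (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow). The same ratio for Gapdh was 0.794 ± 0.00277 and 0.800 ± 0.0148.

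At 8 weeks, for Ccl2, Ubd, Ms4a7, Cxcl2, Timp1, C1s1, Fos, Bub1, Apobec2, Tc2n, Bik, Atf3, Thy1, Dbh and Lcn2 all 3 arrays of at least 1 group lay at or below their array median, so the size of these changes depends on the offset. Altogether 1054 genes were higher and 3226 lower in ICGN at 8 weeks, 24.6% of the calls being higher. With arrays centred on the median of the tested genes 1586 were higher and 2422 lower, with quantile normalization 1699 and 1669, and with the authors' scaling 2215 and 1485, so the balance of the directions depended on the scaling. With the centred arrays 2 proximal tubule genes rose and 26 fell, and 6 podocyte genes rose and 0 fell. Likewise 6 mesangial and smooth muscle genes rose and 1 fell, 3 oxidative stress genes rose and 7 fell, and 1 of the blood and erythroid genes rose and 3 fell. The median tested gene shifted by -0.19 on the log2 scale in the main setting and by 0.05 under the authors' scaling. The lower calls were 2099 without ICR replicate 3 and 2113 without ICGN replicate 1. At a log2 fold change of at least 1 the counts were 387 higher and 348 lower. Of the tensin relatives, Tns1 was lower (-0.48), a call lost under quantile normalization, and Tns3 (-0.18) passed in the main setting and in none of these 3 scalings (camera adjusted p = 0.0197, and adjusted p = 0.164 with an estimated correlation for the 3 tensin genes). The call of Rgs5, a pericyte gene (0.76), was carried by 2 of its 4 probe sets, the others not passing.

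**Figure D2:**
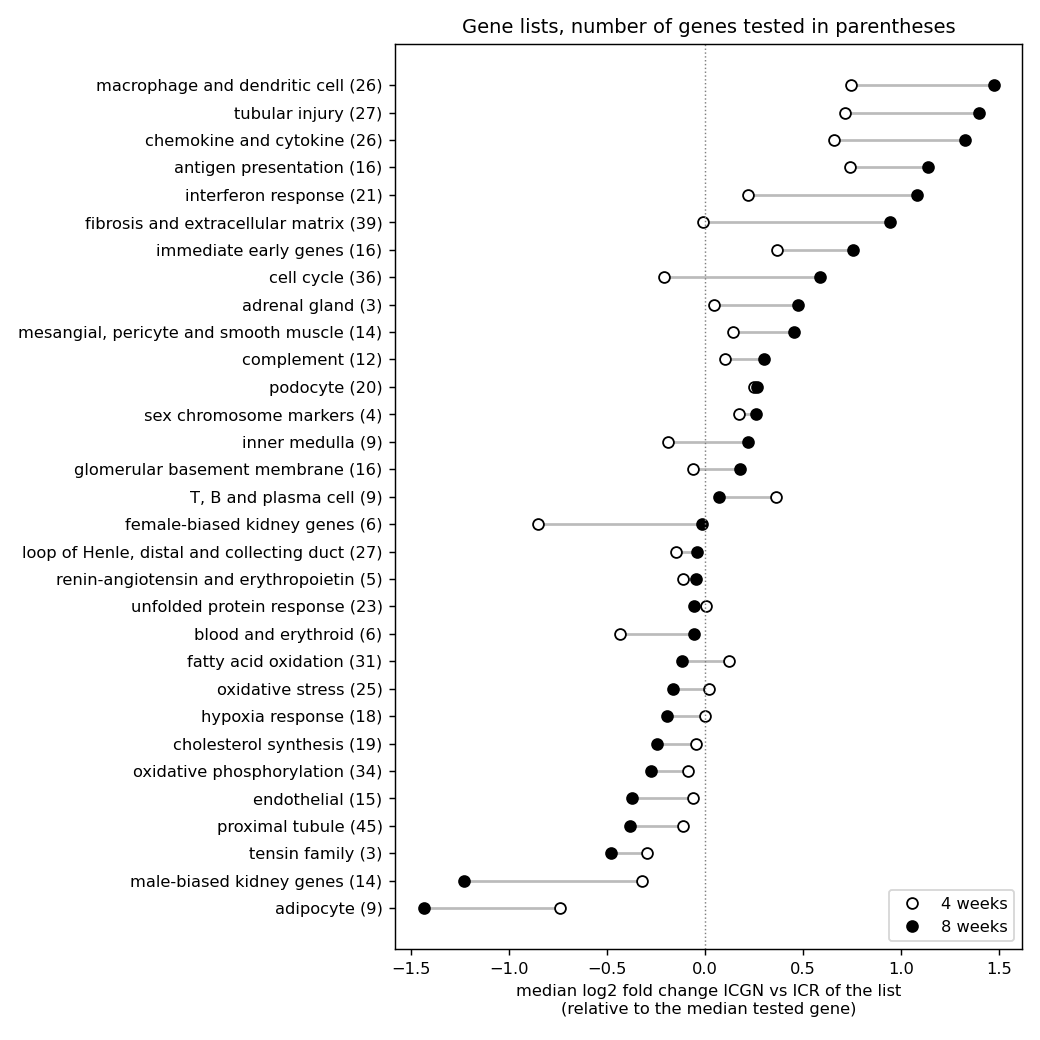
Median log2 fold change of ICGN against ICR, relative to the median tested gene, for 31 gene lists at 4 weeks (open circles) and 8 weeks (filled circles). Injury, immune and matrix lists lie to the right at 8 weeks and the male-biased and adipocyte lists to the left.

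The overlap between the ages asks how far the same genes differed between the strains. Of the 369 genes called at 4 weeks, 243 were called the same way at 8 weeks (65.8%), 123 higher against 16.9 expected of independent lists and 120 lower against 44.5, while 7 were called in opposite directions. Across genes the strain differences at the 2 ages, which share no arrays, correlated with r = 0.444 and rho = 0.335, genes not being independent replicates. Averaged over both ages, Havcr1 (3.93), Lcn2 (3.72), Gdpd3 (3.55), Ubd (3.18), Ccl2 (2.86), Chil4 (2.67), Mid1 (2.51) and the aldo-keto reductase gene Akr1c19 (2.38) were among the highest of the genes called at both ages. C1s1 (-4.02), Dnajc18 (-2.99), Pvalb (-2.36), Bik (-2.35), Clec2h (-2.34), Snap91 (-2.00), Tns2 (-1.92) and the glucagon receptor gene Gcgr (-1.50) were among the lowest of the same genes. The averaged comparison called 955 genes higher and 2344 lower. The counts were 1374 and 2086 with arrays centred on the median of the tested genes, 1517 and 1301 with quantile normalization, and 1984 and 1228 with the authors' scaling. Without ICGN replicate 2 of 4 weeks 116 genes were shared between the ages, and without replicate 1 of that group 131. Without its replicate 3, 81 shared genes were higher, and without ICR replicate 2 or 3 of 4 weeks 78 or 89 were higher and 87 or 74 lower.

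**Figure D3:**
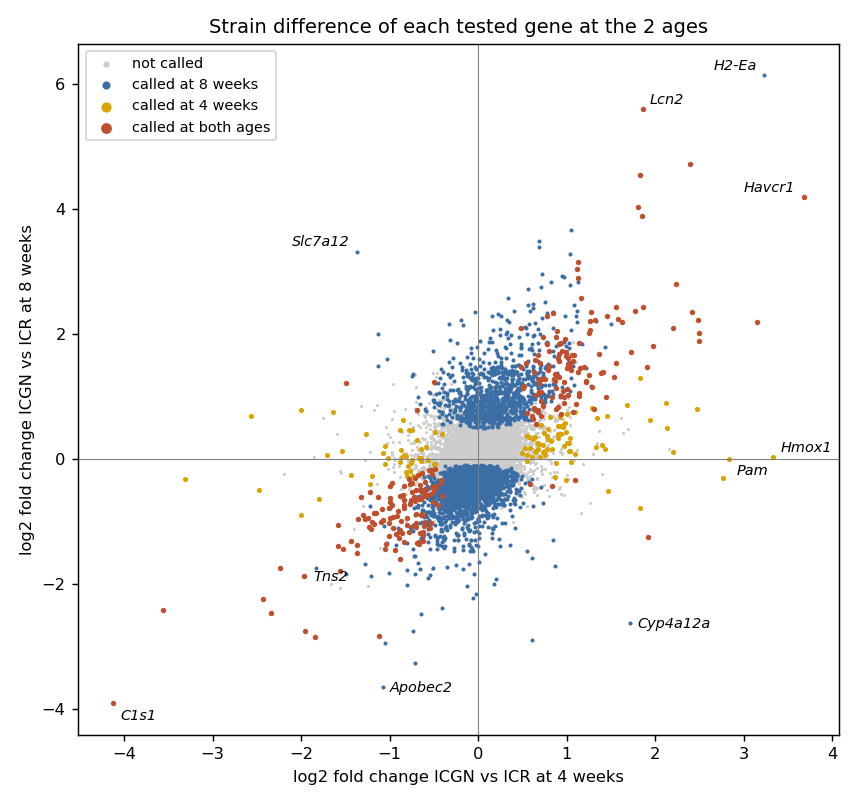
Log2 fold change of ICGN against ICR at 4 weeks (x axis) and 8 weeks (y axis), relative to the median tested gene of each age, for every gene tested; colours give the age at which a gene was called. Havcr1 and Lcn2 lie in the upper right, C1s1 and Tns2 in the lower left, Hmox1 and Pam near 0 at 8 weeks, and lower calls at 8 weeks reach closer to 0 than higher ones because the median shift was subtracted.

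The interaction asks which strain differences changed between 4 and 8 weeks. The female-biased amino acid transporter gene Slc7a12 went from a strain difference of -1.37 to 3.31 (interaction 4.69 ± 0.52, limma adjusted p = 9.8e-04), and the male-biased Cyp4a12a from 1.71 to -2.62 (interaction -4.33 ± 0.64, adjusted p = 0.00213). Neither passed the test at 4 weeks. The difference in Lcn2 widened by 3.74, and that in the transcriptional repressor gene Bcl6 went from -1.13, which did not pass the test, to 2.00 (interaction 3.14), while Hmox1 (-3.31) and Pam (-2.83) lost theirs. Cyp2d9 was higher in ICGN at 4 weeks (1.91) and lower at 8 weeks (-1.25). Among 39 fibrosis and matrix genes 17 had a higher strain difference at 8 than at 4 weeks and 0 a lower one (24 adjusted over the list alone; camera adjusted p = 2.7e-24, and adjusted p = 0.0843 with an estimated correlation). Tubular injury genes followed with 13 higher and 1 lower of 27 (camera adjusted p = 1.6e-13, and adjusted p = 0.161 with an estimated correlation), and cell cycle genes with 6 higher of 36 (camera adjusted p = 2.6e-15, and adjusted p = 0.161 with an estimated correlation), or 14 with arrays centred on the median of the tested genes. From 4 to 8 weeks matrix genes fell in 24 of 39 cases in ICR and rose in 2 (median -0.78). In ICGN 9 rose and 6 fell (median 0.11), so in these values the wider strain difference of matrix genes came mostly with lower values in ICR. The ages had been scaled to separate targets, and age and processing batch cannot be told apart. How the difference divides between the strains is therefore uncertain. Cell cycle genes fell with age in both strains, 34 of 36 in ICR and 32 of 36 in ICGN. In all 271 genes passed the interaction test upwards and 701 downwards. Centring on the median of the tested genes gave 531 higher and 628 lower, quantile normalization 482 and 412, and the authors' scaling 645 and 459. The count fell to 466 without ICGN replicate 2 of 4 weeks, with 469, 473, 559, 594 and 614 without ICR replicate 2 of 4 weeks, ICGN replicate 3 of 4 weeks, ICGN replicate 1 of 8 weeks, ICR replicate 3 of 8 weeks and ICGN replicate 1 of 4 weeks, respectively.

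The change from 4 to 8 weeks in ICR describes the maturing normal cortex. Cyp4a12a rose from 64.0 ± 59.8 to 5912 ± 1532 (93.8-fold on the log scale), Cyp2d9 17.8-fold, Cyp7b1 21.8-fold and Slco1a1 by 3.91 on the log2 scale. The immunoglobulin A heavy chain gene Igha rose by 7.12, Jchain by 5.27 and Igkv8-30 by 5.30, while of 9 lymphocyte and plasma cell genes 3 rose (camera adjusted p = 0.0687). Serpina6, which encodes the corticosteroid-binding globulin, fell 124-fold, Slc7a12 57.8-fold and Cyp4a14 19.7-fold. Cell cycle genes fell in 34 of 36 (34 adjusted over the list alone; camera adjusted p = 1.2e-35, and adjusted p = 0.0453 with an estimated correlation), with Mki67 at -3.19. Fibrosis and matrix genes fell in 24 of 39 and rose in 2 (camera adjusted p = 1.6e-12, and adjusted p = 0.128 with an estimated correlation), Col1a1 at -2.21. Mesangial, pericyte and smooth muscle genes fell in 9 of 14 (camera adjusted p = 2.4e-06, and adjusted p = 0.128 with an estimated correlation) and basement membrane genes in 8 of 16 (camera adjusted p = 6.6e-06, and adjusted p = 0.228 with an estimated correlation), Tagln at -1.68 and Col4a1 at -1.37. Male-biased genes rose in 9 of 14 (camera adjusted p = 3.5e-05, and adjusted p = 0.513 with an estimated correlation) and female-biased genes fell in 4 of 6 (camera adjusted p = 1.6e-04, and adjusted p = 0.0453 with an estimated correlation). In total 2225 genes were higher and 1327 lower at 8 weeks. With arrays centred on the median of the tested genes 2308 were higher and 1784 lower, with quantile normalization 1716 and 2083, and with the authors' scaling 1541 and 2529. Without ICR replicate 3 of 8 weeks 1443 were higher and 1182 lower. In ICR, for Igkv8-30 and Serpina6 all 3 arrays of at least 1 group lay at or below their array median, so the size of these changes depends on the offset. The 2 ages had been scaled to different targets by the authors, so age and processing batch cannot be told apart in either strain.

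In ICGN the same interval brought Jchain (3.11) and Igkv8-30 (3.16) up, together with Clec2d (3.37), Ubd (2.94) and Vcam1 (2.71), with 2 of 9 lymphocyte and plasma cell genes higher (camera adjusted p = 0.0676). Serpina6 (-5.64), Insc (-2.45), Kcne1l (-2.29), Slc22a7 (-2.20), Hmox1 (-2.09) and the aminopeptidase N gene Anpep (-2.07) fell. Macrophage and dendritic cell genes rose in 20 of 26 (24 adjusted over the list alone; camera adjusted p = 6.1e-19, and adjusted p = 0.115 with an estimated correlation), Mpeg1 by 1.63 and Itgax by 1.58. Tubular injury genes rose in 15 and fell in 2 of 27 (camera adjusted p = 6.2e-09, and adjusted p = 0.149 with an estimated correlation), with Lcn2 at 2.40 and the ceruloplasmin gene Cp at 2.27. Antigen presentation genes rose in 11 of 16 (camera adjusted p = 1.9e-07, and adjusted p = 0.276 with an estimated correlation). Cell cycle genes fell in 32 of 36 (camera adjusted p = 9.7e-22, and adjusted p = 0.115 with an estimated correlation), Mki67 at -1.79, and loop, distal and collecting duct genes in 12 of 27 (camera adjusted p = 7.0e-06, and adjusted p = 0.276 with an estimated correlation), Aqp2 at -1.19. Of the matrix genes 9 rose, Dcn by 1.23, and 6 fell (camera adjusted p = 0.121), against 10 and 2 with arrays centred on the median of the tested genes. In total 789 genes were higher and 1586 lower at 8 weeks. The counts were 1371 and 1436 with arrays centred on the median of the tested genes, 1298 and 1942 with quantile normalization, and 1180 and 1820 with the authors' scaling. In ICGN, for Jchain, Igkv8-30, Serpina6, Insc and Kcne1l all 3 arrays of at least 1 group lay at or below their array median, so the size of these changes depends on the offset. The count was 1466 without replicate 1 and 1531 without replicate 2 of the 4-week group (483 and 480 of them higher). Without replicate 3 of 8 weeks 461 were higher and 1696 lower, and the limit on age and batch given for ICR holds here too.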

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

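Tests chosen only after the result was seen are those on the scaling and RNA quality at 8 weeks, those on the sex-biased genes, and those on several or single probe sets per gene, whose rule was changed after the value was seen, while the splits of the arrays and the test on DNA near Tns2 were set out before. The strain difference changed between 4 and 8 weeks, by the interaction test, in named genes whose values are the difference at 8 weeks minus that at 4 weeks on the log2 scale. It was higher at 8 weeks for Slc7a12 (4.69), Lcn2 (3.74), Cd99 (3.25), Bcl6 (3.14), Cyp4a14 (2.80), Atp12a (2.78), Ubd (2.72), H2-DMb2 (2.70), Vcam1 (2.61), Gdpd3 (2.33), Fos (2.24), Aoc1 (2.23), Cyp27b1 (2.15), Ccl2 (2.05), Cfi (1.80), Col3a1 (1.72), Col8a1 (1.55), Rrm2 (1.48), Oasl2 (1.47), Irf7 (1.41), Egr1 (1.41), Mki67 (1.40), Ccnb2 (1.36), Agrn (1.21), Col12a1 (1.18), Mcm5 (1.14), Ctss (1.08), Serping1 (1.01), Tgfbi (0.99), Col18a1 (0.98), Col4a1 (0.89), Mal (0.84) and Vim (0.76). It was lower at 8 weeks for Mvd (-0.42), Dnajc3 (-0.43), Ndufa10 (-0.44), Vegfa (-0.45), Tns1 (-0.49), Ndufv1 (-0.56), Acsm1 (-0.60), Flt1 (-0.67), Sema3g (-0.77), Pvalb (-0.79), Ace (-0.81), Slc7a13 (-0.85), Slc22a6 (-0.86), Cyp51 (-1.03), Kdr (-1.05), Col4a3 (-1.08), Egf (-1.22), Acox3 (-1.41), Aspdh (-1.72), Cndp1 (-1.83), Jchain (-2.16), Slc22a7 (-2.55), Apobec2 (-2.56), Pam (-2.83), Cyp2d9 (-3.16), Hmox1 (-3.31), Tc2n (-3.51) and Cyp4a12a (-4.33). Centring on the median of the tested genes ended the interaction call of Vegfa, Ace, Slc7a13.

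Gene lists past the interaction test at the preset correlation, with their median, were higher at 8 weeks for tubular injury (1.06), fibrosis and extracellular matrix (0.99), female-biased kidney genes (0.85), macrophage and dendritic cell (0.79), interferon response (0.72), cell cycle (0.69), chemokine and cytokine (0.66), immediate early genes (0.50), antigen presentation (0.41), mesangial pericyte and smooth muscle (0.34), complement (0.32) and glomerular basement membrane (0.17), and lower for oxidative phosphorylation (-0.17), oxidative stress (-0.19), endothelial (-0.23), cholesterol synthesis (-0.24), hypoxia response (-0.25), proximal tubule (-0.27) and male-biased kidney genes (-0.63). No list passed this test with an estimated correlation. Among data outside the gene counts, 648 of 2964 probe sets without a single gene symbol were called in the strain comparison at 8 weeks, 234 higher and 414 lower. The 18S ribosomal RNA control probe set read 1310.2 in ICGN replicate 2 of 8 weeks, against 421 and 517 in its group, and 3511 genes were called at 8 weeks without that array.

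Other splits of the arrays were counted for each result. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 369 genes at 4 weeks and the highest other 1, 4280 and 0 at 8 weeks, 3552 and 3 for age in ICR, and 2375 and 0 for age in ICGN, in each case 1 split reaching the real count. For the lists the real split passed 14 at 4 weeks and another 12, 17 and 17 at 8 weeks, 12 and 18 in ICR, and 18 and 20 in ICGN, so 1, 2, 3 and 2 splits reached it. Of 100 splits within ages, 1 reached the 3299 genes of the mean of both ages (highest other 2739) and 1 the 243 genes shared by the ages (highest other 7). For the lists of the interaction 1 reached the 19 of the real split (highest other 18). By the share set beforehand chance is argued against for the genes of the mean and for those shared by the ages. The lists met that share only by a margin of 1 at the preset correlation. None of them passed with an estimated correlation, so no conclusion is drawn from their count. For the interaction 11 splits reached the 972 genes, so it did not meet the share set beforehand and chance is not argued against. The count cannot decide on chance either way, since splits within ages can keep the strain grouping at 8 weeks and so carry that strain difference. The highest count among these splits, 3299, came from the split that mirrors the strains at one age, which carries the strain difference itself.

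At 8 weeks more genes were lower than higher in ICGN. The scaling of the arrays may account for this balance, since over 4 scalings of the same signals the share of higher calls ranged from 24.6% to 59.9%. A difference in RNA quality cannot be told apart from the strains at this age. The 3' to 5' ratio did not overlap between them for 1 of 3 control transcripts, Actb, while Gapdh and Pcx (7.73 ± 1.85 in ICGN and 8.05 ± 1.21 in ICR) overlapped. A true excess of lowered genes stays open as well.

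Male-biased genes were lower in ICGN at 8 weeks, with a median of -1.23. Female mice among the samples are argued against by Y-linked genes, whose median strain difference was 0.31, and by Xist. In these arrays the male-biased median lay -0.86 from that of 44 other proximal tubule genes (95% interval -1.02 to -0.21 by a bootstrap over genes). The bootstrap held the arrays fixed and took genes as independent, while the male-biased list had an estimated correlation of 0.56. It does not measure the spread between arrays, so a general fall of proximal tubule genes is not excluded as the whole cause. A delay of sex maturation present by 4 weeks cannot be told apart. At that age the male-biased median (-0.32, mean -0.12) lay the way a delay predicts, with 1 gene called higher and 1 lower. Against that median, Cyp2d9 (1.91) and Cyp4a12a (1.71, which did not pass) lay higher in ICGN, though both rose steeply with age in ICR. The male-biased list did not pass (camera adjusted p = 0.0804, and adjusted p = 0.84 with an estimated correlation). The female-biased list lay the other way from a delay (median -0.86, camera adjusted p = 0.00115, and adjusted p = 0.0704 with an estimated correlation). Its called gene, Rnf24, was lower in ICGN at both ages (-1.57 and -1.79). Of 13 sex-biased genes that changed with age in ICR, 12 went the same way and less far in ICGN, which restates the pattern and does not test its cause. So did 2358 of 3539 other genes that changed with age in ICR (66.6%).

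A set of 70 genes differed between the strains by at least 1 on the log2 scale at both ages and did not pass the interaction test. Of these 47 were higher in ICGN, Havcr1, C1qa and Cd74 among them, and 23 lower, including C1s1, Dnajc18 and Tns2. Sequence differences under single probe sets are argued against for most of the 22 genes with several tested probe sets, of which 81.8% (exact 95% interval 59.7% to 94.8%) had other probe sets with at least 50% of the difference. That share pools the higher and the lower genes. Of the lower genes, Bik, Dnajc18, Clec2h, Tfrc and Fgf1 had such other probe sets, while Cnnm4 and Lin7a did not. These are too few to judge the lower genes alone. Of the higher genes, Serpinb1a and H2-D1 did not. Among 18 injury and inflammation genes with another tested probe set, which share members with the set, the share was 94.4%. For the 48 genes with 1 tested probe set, C1s1 and Tns2 included, sequence and level cannot be told apart, because no other probe set was there to compare. DNA carried along with Tns2 is argued against as the source of most of the set, since 0 of its 69 other genes with a position lay among the 100 tested genes nearest to Tns2 (exact 95% upper limit 5.21%), while the test of enrichment there (Fisher's exact test, one-sided p = 1) had little power, the share elsewhere being 0.563%. Bik, Nipal2, Osmr, Myc and Fyb lie on the chromosome of Tns2 outside those 100 genes. The length of a linked stretch is not known, so a longer one is not excluded for them. The strains may also differ at many loci unlinked to Tns2, which the design does not separate from the disease.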

How the results depend on the processing

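The authors' scaling was tried only after seeing the data. With a log2 fold change of at least 1 required, calls fell to 143 at 4 weeks, 735 at 8 weeks, 306 for the mean, 333 for the interaction, 759 and 423 for age in ICR and ICGN, and 82 for the overlap, by construction. Quantile normalization gave 560 calls at 4 weeks, and every probe set on its own 6009 and 4284 for age in ICR and ICGN, more items being tested. Lists past the test fell with an estimated correlation to 0, 4, 0, 2 and 0 at 4 weeks, at 8 weeks, for the interaction and for age in ICR and ICGN, and with fry to 7 at 4 weeks and 9 for the interaction. Leaving out each array gave 167 to 415 genes at 4 weeks, 3027 to 4253 at 8 weeks, 2455 to 3486 for the mean, 466 to 1051 for the interaction, 2598 to 3809 and 1466 to 2465 for age in ICR and ICGN, 116 to 257 for the overlap, and 12 to 17, 16 to 17, 15 to 20, 9 to 16 and 17 to 21 lists in the order above. The other settings kept every such count within 1.5 times. Single probe sets turned the sign of called values at 4 weeks for Adi1 -0.59, H2-D1 -4.13, -4.08, -3.78, at 8 weeks for Rgs5 -0.11, -0.12, Dnajc3 0.18, in ICR for Tns1 -0.39, -0.67, Trpm6 0.21, Cybb -0.28, Pfkl 0.63, Uty -2.14, Dgat2 -0.58, and in ICGN for Lamc1 0.35, Eng 0.29, Col8a1 -0.13, Xbp1 -0.045, Pfkl 0.43; the mean of probe sets did so for H2-D1 -0.90 at 4 weeks and Tns1 -0.24, Uty -0.36, Dgat2 -0.12 in ICR. The oxidative phosphorylation list changed direction at 4 weeks under quantile normalization (adjusted p = 0.667). The cause was not tested. Of 374 named values, 3 lost their call when arrays were centred on the median of the tested genes, 11 under the authors' scaling, 9 under quantile normalization, 27 without the filter and 5 without the offset. Among named values recomputed without 1 array, 287 lost their call and 4201 did not. Replicate number as a block gave 393 genes at 4 weeks, 4529 at 8 weeks and 1318 for the interaction, against 369, 4280 and 972 without it. With the block 2 named values lost their call. Same-numbered arrays deviated from their groups with correlations between -0.10 and 0.11, 1 of 18 pairs over 0.1. Of 12 arrays 5 correlated best with their own number. These correlations show no clear pairing by number, but the counts with the block were higher, so a pairing is not excluded. Signals near the array median limit what can be read of dim genes.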

Other observations

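The single genes given here, most of them outside the lists, were chosen after their values were seen, and no group of them was tested. At 8 weeks the vitamin D receptor gene Vdr was lower in ICGN (-0.93, limma adjusted p = 6.9e-05), as were Kl, which encodes klotho, a co-receptor for a phosphate-regulating hormone (-0.56, adjusted p = 0.00246), and the phosphate cotransporter genes Slc34a1 (-0.40, adjusted p = 0.00205) and Slc34a3 (-0.80, adjusted p = 0.00114). Cyp27b1, which encodes the enzyme that activates vitamin D, was higher at that age (2.71), and Cyp24a1 did not pass (adjusted p = 0.263). Vdr (0.11) and Kl (-0.07) did not pass the test at 4 weeks, nor did Slc34a1 and Slc34a3, and the interaction passed for Vdr (-1.03, adjusted p = 0.00493) and not for the other 3.

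Scd1, which encodes a fatty acid desaturase, was higher in ICGN (1.86 at 4 weeks and 2.42 at 8 weeks), as was the cholesterol exporter gene Abca1 (1.07 and 1.57). The transferrin receptor gene Tfrc was lower at both ages (-1.53 and -1.45), with signals of 589 ± 56.9 in ICGN and 1840.4 ± 58.7 in ICR at 8 weeks. None of these 3 genes passed the interaction test.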
